A study of Mus musculus with 9 samples.

How the data were processed

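Bulk RNA sequencing was done on hippocampal cells in 9 libraries, 3 for each of 3 groups that the labels give as 3 mice each: wild-type mice after a sham operation, wild-type mice after mild traumatic brain injury (mTBI, a single mild controlled cortical impact), and mice with a conditional knockout of Tmsb4x after the same injury. Per the labels, the cells were dissociated with trypsin and sorted live on the red fluorescent protein tdTomato, which the mice express in neurons, and the libraries were sequenced on a NovaSeq 6000 as paired-end reads of 150 bp. The labels give neither the sex of the mice, the time after injury nor the part of Tmsb4x that was deleted. No group holds knockout mice after a sham operation, so an interaction of genotype with injury could not be tested.

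The deposited values are raw counts of reads per Ensembl gene, without normalization, in 1 table of 55421 genes and 9 libraries. Per the file headers, the authors made it with featureCounts 2.0.6 over the exons of Ensembl release 98 on mouse genome GRCm38. The processing notes also name FastQC, Trim Galore, HISAT2, SAMtools and MultiQC, without versions, and genome mm10. The command held no option for counting read pairs as 1 fragment, none for strand and none for reads with several alignments, so by the defaults of that version both mates of a pair were counted singly, strand was ignored and multi-mapping reads were left out. The share of even counts was 58.7% to 60.3% per library, and a median of 680 genes per library had 1 count against 2798 genes with 2 counts. Symbols, positions and exon lengths were taken from GENCODE M21 (Ensembl 96, GRCm38) by Ensembl identifier, which matched 55240 of the 55421 genes.

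Totals were 36452443 to 39590872 counts per library, with 25981 to 26857 genes having at least 1 count. Levels are given as CPM, counts scaled to a common library total, with TMM factors, as mean and SD of 3 libraries. Genes were filtered with filterByExpr, which left 20032 genes, and tested with the two-sided quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. The fit held all 9 libraries with 1 spread shared by the groups, 6 residual and 5.12 prior degrees of freedom, and a common biological coefficient of variation of 15.3%. The p-values were adjusted by Benjamini-Hochberg over all genes tested in a comparison, and a gene was called at an adjusted p under 0.05, with no fold minimum. The comparisons were wild-type mTBI minus sham, knockout mTBI minus wild-type mTBI, and knockout mTBI minus sham. An exact two-sided permutation test of 3 against 3 libraries, whose smallest p is 0.1, was added for Tmsb4x.

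Gene lists of cell types and cell processes were written before the data were examined, as were the tests, the named-gene rule and the first set of alternative settings. Of these, 44 lists with at least 3 tested genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 44 lists of a comparison. Camera compares a list with all other genes. An estimated correlation and fry, which tests whether the genes of a list move on balance one way, were the alternatives. Counts of called members are given over all genes and adjusted over the list alone. The sex-linked list of 6 genes was only shown per library.

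Genes were named by the following rule. Tmsb4x and its paralog Tmsb10 were named throughout. In the injury and the knockout comparison, the 10 higher and 10 lower genes of smallest p were named among called genes with a mean count of at least 20, with groups not overlapping in CPM (a condition that 10% of unchanged genes meet by chance with 3 against 3), and with a symbol other than a predicted gene, RIKEN clone or pseudogene. Where fewer than 5 passed in a direction, the 5 of smallest p were named as not passing. In the comparison of the injured knockout with sham, 5 genes were taken per direction. Up to 4 members of smallest p were taken from each list described, up to 10 genes called in opposite directions, and the 2 most abundant markers of each non-neuronal cell type.

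Alternatives were RLE scaling, no composition scaling, DESeq2 1.42.0, limma voom with sample quality weights, no count filter, a stricter filter, a fit of the 6 libraries compared, the replicate number as a block, a fold minimum, totals without mitochondrially encoded, haemoglobin and ribosomal RNA genes, and each of the 9 libraries left out in turn. A further 5 alternatives were chosen after the data were seen: counts divided by 2 and rounded, the sham libraries summed to 1 sample, voom with a weight per group, a choroid plexus covariate, and wild-type mTBI replicate 1 and knockout mTBI replicate 1 left out together. The relation between the injury and the knockout comparison, which share the wild-type mTBI libraries, was set against 20 simulated data sets without any difference between groups. The edgeR test was tested on simulated data for the 20032 genes of each comparison, with 1 spread per gene shared by all groups. The real groups differed in spread, so the shares and false calls hold for equal spread only. In the injury comparison it recovered 35.8% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 93.9% of those changed 4-fold, with 3 false calls. For the knockout comparison these shares were 32.8%, 67.2% and 93.9%, with 10 false calls, and for the injured knockout against sham 31.3%, 70.1% and 92.4%, with 5 false calls. Counts of reads are not independent molecules, so the counting error of the files understates that of the RNA. Some genes that were tested are not reported here.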

Results

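The data were gene counts of sorted hippocampal cells, in libraries labelled as 3 wild-type sham, 3 wild-type mTBI and 3 Tmsb4x-knockout mTBI mice. Totals lay between 36452443 and 39590872 counts per library. Mitochondrially encoded genes took 4.32% to 5.57% of counts. Neuronal transcripts were abundant, with Camk2a at 4330 ± 442 CPM (SD, n = 9) and Snap25 at 1792 ± 162 CPM. Transcripts of other cell types were abundant as well, although the labels describe a sort for neuronal fluorescence. The myelin gene Mbp stood at 3085 ± 480 CPM over the 9 libraries, and the astrocyte genes Slc1a2 and Aldoc at 2637 ± 308 and 736 ± 78.4 CPM. Wild-type mTBI replicate 3 held 834 CPM of Xist, transcribed from the inactive X chromosome, and 0.050 CPM of the Y-linked gene Ddx3y. The other 8 libraries held at most 0.892 CPM of Xist and between 49.6 and 58.6 CPM of Ddx3y. By these genes, wild-type mTBI replicate 3 came from a female mouse and the other 8 libraries from males. No fit held sex, which was unbalanced in the comparisons that use wild-type mTBI.

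The 3 libraries labelled wild-type sham were closer to one another than the libraries of the other groups. Their biological coefficient of variation was 3.11%, against 16.9% in wild-type mTBI and 15.0% in knockout mTBI. Over 13479 genes, the variance between 2 sham libraries was 1.46 to 1.59 times that of counting noise, allowing 2 counts per fragment. In wild-type mTBI it was 11.2 to 42.4 times that noise, and in knockout mTBI 12.9 to 24.4 times. Whether the sham libraries were 3 mice, as labelled, or technical replicates of 1 pool was not settled by the tables. Every SD, p and count against sham below takes them as 3 mice, and would not hold as given for technical replicates. The spread shared by the groups also draws on the sham libraries. The p-values of knockout mTBI against wild-type mTBI therefore carry the same limit. The first principal component held 27.8% of the variance, and wild-type mTBI replicate 1 lay at -59.0 on it, with the other 8 libraries between -21.5 and 33.2.

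Tmsb4x encodes the actin-monomer-binding peptide thymosin beta 4 and is the gene deleted in the knockout. Its level (ENSMUSG00000049775, GRCm38 chromosome X, 167207093 to 167209315, minus strand) was 583 ± 302 CPM (SD, n = 3) in wild-type mTBI. It was 2.46 ± 0.549 CPM in knockout mTBI and 2.21 ± 0.523 CPM in the libraries labelled wild-type sham. The 3 wild-type mTBI libraries held 35061, 21678 and 11921 counts, the knockout libraries 70, 109 and 108, and the sham libraries 105, 61 and 85. Tmsb4x was 263-fold higher in wild-type mTBI than in sham (log2 8.04, SE 0.43, adjusted p = 1.89e-05) and 236-fold lower in knockout mTBI than in wild-type mTBI (log2 -7.88, SE 0.43, adjusted p = 2.07e-05). Knockout mTBI and sham differed by log2 0.15 (SE 0.43, adjusted p = 0.999), a difference whose sign turned without sham replicate 2 (log2 -0.0059). The exact permutation test gave p = 0.1 for the first and second of these comparisons, the smallest it can give, and 0.5 for the last. Because sham was at the level of the knockout, directions against sham below are given for the libraries labelled wild-type sham. Tmsb10, the paralog, differed by log2 0.35 (SE 0.13, adjusted p = 0.268) after injury and by -0.28 (SE 0.13, adjusted p = 0.732) with the knockout, and neither passed.

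**Figure D1:**
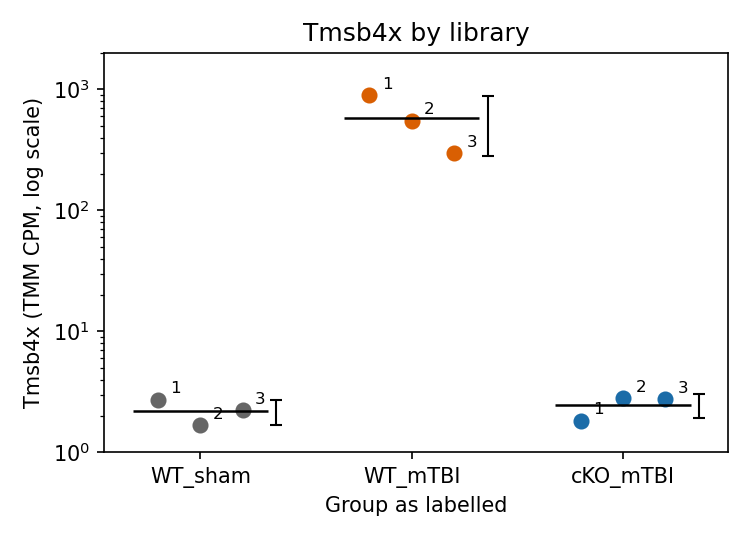
Tmsb4x level (TMM-scaled CPM, log axis) in each library by labelled group. Points are libraries with their replicate numbers, lines are means of 3 and bars at the right of each group are 1 SD. The wild-type mTBI libraries sit between 297 and 900 CPM, and the sham and knockout libraries between 1.68 and 2.79 CPM.

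The first comparison asked which genes differed after injury in wild-type mice. Choroid plexus genes were higher in wild-type mTBI than in the libraries labelled wild-type sham. Ttr, the thyroid hormone carrier of cerebrospinal fluid, rose from 17.1 ± 0.541 to 3700 ± 638 CPM (n = 3 each, log2 7.76, SE 1.30, adjusted p = 0.0373). The homeobox gene Otx2 (chromosome 14, 48657677 to 48673819) rose from 0.832 ± 0.264 to 12.8 ± 2.47 CPM (log2 3.94, adjusted p = 0.00139). Enpp2, the enzyme autotaxin, rose from 171 ± 0.276 to 1569 ± 318 CPM (adjusted p = 0.0373), and the folate receptor gene Folr1 from 0.680 ± 0.278 to 25.9 ± 4.19 CPM (adjusted p = 0.0433). All 10 members of the ependymal and choroid list had positive changes, with a median of log2 2.80. Of these, 4 were called over all genes and 7 adjusted over the list alone. Ttr, Enpp2 and Folr1 lost their calls without any one of sham replicates 1, 2 and 3, wild-type mTBI replicates 2 and 3 and knockout replicate 3, at adjusted p between 0.0501 and 0.258. Folr1 also had 0.0511 with a stricter filter and 0.0504 in voom with a weight per group. The list was called at adjusted p = 3.55e-08, with adjusted p = 0.950 with an estimated correlation. In knockout mTBI, Ttr stood at 3395 and 2746 CPM in replicates 2 and 3 and at 22.99 CPM in replicate 1.

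Other named genes were higher as well. Epn3, an endocytic adaptor of the epsin family, was 5.34-fold higher in wild-type mTBI than in sham (log2 2.42, SE 0.16, adjusted p = 6.87e-05). Sfrp5, a secreted Wnt antagonist, was 12.5-fold higher (adjusted p = 0.0017) and Pcp4l1 1.92-fold higher (adjusted p = 0.00139). These 3 genes were about as high in knockout replicate 1, where the choroid list had a median of log2 0.010 above sham, as in replicates 2 and 3. In replicate 1 they stood at log2 1.94, 3.32 and 0.82 above sham, with Otx2 at 2.62, and all 4 kept their calls with a choroid covariate. Within groups, the choroid list varied mostly through knockout replicate 1, at 0.010 against 2.77 and 2.39 in replicates 2 and 3. The covariate therefore rests largely on that library. Calls kept or lost with it, here and below, cannot isolate the share of choroid genes. Otx2, itself a member of the list whose mean is the covariate, went from log2 3.94 to 2.53 with it. The secreted phospholipase Pla2g5 was 8.65-fold higher, the serine protease inhibitor Serpinb1b 6.06-fold, the growth factor carrier Igfbp2 3.51-fold and the lysosomal tetraspanin Cd63 1.45-fold, at adjusted p between 0.00411 and 0.0152. With a choroid covariate these lost their calls. Pla2g5 went from log2 3.11 to 2.21 (SE 0.33 to 0.50, adjusted p = 0.163), Serpinb1b from 2.60 to 1.87 (SE 0.30 to 0.51, adjusted p = 0.246), Igfbp2 from 1.81 to 0.78 (SE 0.20 to 0.15, adjusted p = 0.0942) and Cd63 from 0.54 to 0.50 (SE 0.07 to 0.14, adjusted p = 0.279). In Cd63 the call ended with the larger SE, in Igfbp2 with the smaller change, and in the others with both. Among the genes that fell, Pura (chromosome 18, 36281097 to 36292535), a nucleic acid-binding protein of neurons, went from 74.7 ± 2.74 to 35.3 ± 5.10 CPM (log2 -1.08, SE 0.12, adjusted p = 0.00637). The zinc finger gene Zfp949 changed by log2 -1.54, the guanylate cyclase subunit Gucy1a2 by -1.95, the corticotropin-releasing hormone binder Crhbp by -0.76 and the homeobox gene Onecut2 by -0.69. The protocadherin Pcdh19, the lipoprotein receptor Lrp1b, Nbeal1 and the potassium channel-interacting protein Kcnip3 changed by log2 -0.50, -0.63, -0.56 and -0.35. The adjusted p of these last 8 genes lay between 0.0176 and 0.0408, and between 0.0825 and 0.568 with a choroid covariate. The SE of all 8 grew with the covariate while 7 of the changes stayed or grew, such as Zfp949 at log2 -2.04 (SE 0.21 to 0.38) and Kcnip3 at -0.35 (SE 0.06 to 0.13). Only Crhbp shrank, to -0.43. In knockout replicate 2, Zfp949 was at 45.4 CPM, between sham (63.6 to 68.1) and the other injured libraries (21.1 to 25.6). Whether this pattern came from injury or from another difference between the mice was not tested.

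In all, 102 of 20032 genes were called after injury, 77 higher and 25 lower, and 70 of them differed more than 2-fold (edgeR). A total of 2653 genes had an unadjusted p under 0.05. Among the 77 higher genes, 59 were raised by over 50% of the log2 change in both knockout mTBI replicates 2 and 3, and 42 of these were not raised so in replicate 1. The count was lower with fewer sham libraries, which also left fewer samples to test: it was 5 without sham replicate 1 or without sham replicate 2, 9 without sham replicate 3, and 1, Tmsb4x, with the sham libraries summed. Tmsb4x, Epn3, Pcp4l1, Otx2 and Sfrp5 were the 5 genes kept without sham replicate 1 and without sham replicate 2, and none of the 9 named lower genes kept its call in either. Their changes moved little, Pura being at log2 -1.07 and -1.06 against -1.08. The count was 26 without wild-type mTBI replicate 3, 251 without knockout replicate 1, 38 without knockout replicate 3, 45 with a choroid covariate, and 524 without wild-type mTBI replicate 1 and knockout replicate 1 together. Without wild-type mTBI replicate 2 the count was 93 with 45 higher and 48 lower, so the excess of higher genes was not kept there.

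The nuclear genes of the respiratory chain were higher in wild-type mTBI than in the libraries labelled wild-type sham, with 44 of 44 positive and a median of log2 0.24 (adjusted p = 1.97e-09, or 0.950 with an estimated correlation). Cox5b, a subunit of cytochrome c oxidase, was at 183 ± 28.9 against 132 ± 1.16 CPM (adjusted p = 0.0969) and Cox6a1 at 204 ± 28.0 against 159 ± 6.29 CPM (adjusted p = 0.119). No member was called over all genes and 2 were adjusted over the list alone. Genes of cytosolic ribosomal proteins had a median of log2 0.25 with 40 of 42 positive (adjusted p = 1.32e-07, or 0.950 with an estimated correlation), Rplp2 being at 116 ± 22.3 against 87.2 ± 2.27 CPM (adjusted p = 0.151). These lists stood at log2 0.55 and 0.57 above sham in wild-type mTBI replicate 1, and at 0.069 to 0.096 in replicates 2 and 3. Without replicate 1 the medians were 0.081 and 0.086, and both lists stayed called (adjusted p = 2.87e-05 and 0.00088).

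Lysosomal genes had a median of log2 0.12 with 22 of 26 positive (adjusted p = 0.000687, or 0.950 with an estimated correlation). Cd63 was called over all genes and 7 were called adjusted over the list alone, among them the proteases Ctsl (log2 0.45, adjusted p over all genes 0.0514) and Ctsd (0.54, 0.0716). With a choroid covariate this list had adjusted p = 0.343. Antioxidant genes of the NRF2 list had 19 of 21 positive and a median of log2 0.21 (adjusted p = 0.00111, or 0.950 with an estimated correlation), with 4 higher adjusted over the list alone, Gpx4 at log2 0.44 (adjusted p = 0.105) and Nqo1 at 0.76 (adjusted p = 0.206). The NRF2 list stood at log2 0.33 above sham in wild-type mTBI replicate 1, at 0.058 in replicate 2 and at 0.12 in replicate 3. Targets of the actin-responsive factor SRF had 13 of 16 positive, a median of log2 0.18 and adjusted p = 0.0196, which was 0.950 with an estimated correlation, 0.0649 without sham replicate 1 and 0.126 without wild-type mTBI replicate 3. Genes of actin dynamics had 27 of 33 positive and a median of log2 0.10 (adjusted p = 0.0326, or 0.950 with an estimated correlation), with Actg1 at 543 ± 49.8 against 393 ± 9.77 CPM (adjusted p = 0.0579) and Actb at 1257 ± 193 against 940 ± 6.85 CPM (adjusted p = 0.0894). The actin list had adjusted p = 0.560 without wild-type mTBI replicate 1, 0.0649 without sham replicate 1, 0.0597 without knockout replicate 1, 0.356 with a choroid covariate, 0.0561 with a stricter filter and 0.638 without wild-type mTBI replicate 1 and knockout replicate 1 together.

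The lists of postsynaptic glutamate and voltage-gated channel genes were lower in wild-type mTBI than in the libraries labelled wild-type sham, while the presynaptic (adjusted p = 0.658) and GABA signalling (0.739) lists did not pass. Postsynaptic glutamate genes had 22 of 27 negative changes and a median of log2 -0.18 (adjusted p = 2.68e-06, or 0.950 with an estimated correlation). None was called over all genes and 4 were lower adjusted over the list alone. The adhesion gene Nlgn1 was at 71.1 ± 8.39 against 91.3 ± 2.06 CPM (adjusted p = 0.105) and the receptor gene Grin2a at 305 ± 45.7 against 397 ± 9.77 CPM (adjusted p = 0.157). Voltage-gated channel genes had 20 of 23 negative and a median of log2 -0.22 (adjusted p = 4.52e-05, or 0.950 with an estimated correlation), with 4 lower adjusted over the list alone. Kcnh7 was at log2 -0.38 (adjusted p = 0.0607) and Cacna1e at -0.46 (adjusted p = 0.206). The channel list stood at log2 -0.57 from sham in wild-type mTBI replicate 1, at -0.13 in replicate 3 and at -0.01 in replicate 2. The postsynaptic list stood at -0.32, -0.15 and -0.08 in the same order. Replicate 1 also had a rank correlation of -0.29 between level relative to the mean and exon length across genes. Whether length contributed to these lists was not tested.

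Lists of resident cell types did not pass after injury. Adjusted p was 0.658 for neuronal markers (median log2 -0.04), 0.563 for astrocyte markers (-0.05), 0.968 for microglial markers, 0.563 for oligodendrocyte markers (0.16) and 0.812 for endothelial markers (-0.04). Astrocyte markers went both ways, with 2 higher and 3 lower adjusted over the list alone and adjusted p = 0.000382 in the mixed fry test, which asks for change in either direction. The endothelial list held 1 called gene, Bsg, at 459 ± 40.2 against 338 ± 10.0 CPM (log2 0.44, adjusted p = 0.0490). Median, mean and test differed in sign for 8 lists, none of them called: those of microglia (a median of log2 0.02 with a negative test direction), microtubules, iron and ferroptosis, mitochondrially encoded chain subunits, presynaptic genes, GABA signalling, immature neurons and proliferation. The immediate early list had a median of log2 0.32 with 17 of 25 positive and adjusted p = 0.102, and the cholesterol synthesis and p53 lists both had adjusted p = 0.0501. Of the 44 lists 9 were called, 7 higher and 2 lower. That count was 13 without wild-type mTBI replicate 2, 14 without wild-type mTBI replicate 3, and 7 without sham replicate 1.

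**Figure D2:**
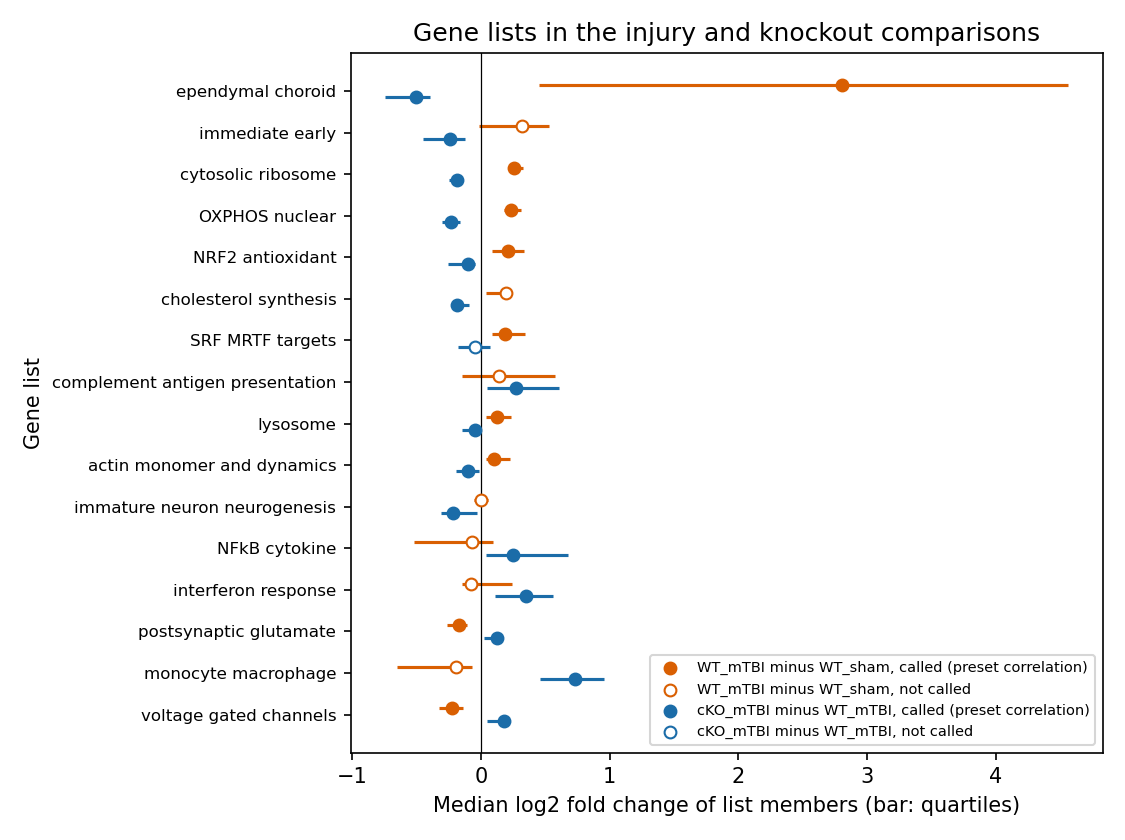
Median log2 fold change of the members of each list called in the injury or the knockout comparison, with bars from the first to the third quartile of members. Filled points were called with the preset correlation and open points were not, and none was called with an estimated correlation. The ependymal and choroid list lies at 2.80 after injury and at -0.50 for the knockout, and the respiratory chain list at 0.24 and -0.24.

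The second comparison asked which genes the knockout altered in injured mice. Besides Tmsb4x, 2 genes passed. Etnppl, an astrocyte-enriched lyase of phosphoethanolamine (chromosome 3, 130617448 to 130637521), was at 36.6 ± 3.32 CPM in knockout mTBI and 18.0 ± 1.14 CPM in wild-type mTBI (SD, n = 3 each, 2.04-fold higher, log2 1.03, SE 0.09, adjusted p = 0.00299). Myoc, the secreted glycoprotein myocilin (chromosome 1, 162639155 to 162649693), was at 12.8 ± 1.70 against 26.3 ± 3.82 CPM (2.06-fold lower, log2 -1.04, SE 0.13, adjusted p = 0.0380). The immediate early gene Nr4a2 was at 38.0 ± 1.22 against 53.8 ± 0.364 CPM and missed the threshold (adjusted p = 0.0575). Other genes of smallest p did not pass: Hif3a (log2 0.97), the lysozyme gene Lyz2 (0.85), Rtp1 (1.71) and the Polycomb gene Cbx7 (0.39) on the higher side, and Vill (-1.31), Cd63 (-0.38), Id3 (-0.46) and Actg1 (-0.46) on the lower side. Their adjusted p was 0.421 for Vill, 0.719 for Cd63 and 0.732 for the rest.

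The 3 called genes were 1 higher and 2 lower, with 1323 genes at an unadjusted p under 0.05 (edgeR). Tmsb4x kept its call in every alternative run, between log2 -8.20 and -7.25. In the fit of the 6 libraries compared and with the sham libraries summed, Etnppl (adjusted p = 0.0718 and 0.0769) and Myoc (0.487 and 0.476) lost their calls. The Myoc call also ended without any one of sham replicates 1, 2 and 3, wild-type mTBI replicates 1 and 3, or knockout replicates 1 and 2, with log2 between -1.04 and -0.95, and with a choroid covariate (log2 -1.03, SE 0.13 to 0.16, adjusted p = 0.116). The count was 5 without wild-type mTBI replicate 1, 7 without wild-type mTBI replicate 3 (6 higher and 1 lower), 23 without wild-type mTBI replicate 1 and knockout replicate 1 together, and 18 in DESeq2.

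Several lists were lower in knockout mTBI than in wild-type mTBI, and the respiratory chain list was the first of them by p. All 44 of its genes had negative changes, with a median of log2 -0.24 (adjusted p = 2.07e-12, or 0.686 with an estimated correlation), with Cox6a1 at 160 ± 5.23 against 204 ± 28.0 CPM. The median was -0.079 without wild-type mTBI replicate 1, with adjusted p = 2.78e-06. The ribosomal protein list had a median of log2 -0.19 (adjusted p = 5.55e-07, or 0.686 with an estimated correlation), and the immediate early list, with Egr1 at 73.9 ± 19.6 against 121 ± 42.3 CPM, had 22 of 25 negative and a median of -0.24 (adjusted p = 4.75e-06, or 0.686 with an estimated correlation). The actin list had 26 of 33 negative and a median of log2 -0.11 (adjusted p = 0.00119, or 0.686 with an estimated correlation), Actb being at 931 ± 24.4 against 1257 ± 193 CPM. Without wild-type mTBI replicate 1 the adjusted p was 0.291 for the ribosomal, 0.119 for the immediate early and 0.135 for the actin list. Without knockout replicate 1 as well it was 0.961, 0.145 and 0.416.

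Of the further lists that were lower, cholesterol synthesis had 19 of 22 negative and a median of log2 -0.19 (adjusted p = 9.50e-05, or 0.686 with an estimated correlation), with Hmgcs1 at 143 ± 26.5 against 184 ± 26.3 CPM, and adjusted p = 0.172 without knockout replicate 2. Antioxidant genes had a median of log2 -0.10 (adjusted p = 0.00119, or 0.686 with an estimated correlation), with Prdx1 at log2 -0.33. From sham, the antioxidant list stood at log2 0.036, 0.042 and 0.0050 in knockout replicates 1, 2 and 3. In wild-type mTBI replicates 1, 2 and 3 it stood at 0.33, 0.058 and 0.12. Immature neuron genes had a median of log2 -0.22 (adjusted p = 0.00842, or 0.686 with an estimated correlation), with Hopx, a marker of neural stem cells, at log2 -0.69 and Eomes, a marker of neuronal progenitors, at 0.98. That list had adjusted p = 0.139 without wild-type mTBI replicate 3 and 0.0695 without knockout replicate 2. The ependymal and choroid list had 10 of 10 negative and a median of log2 -0.50 (adjusted p = 0.000462, or 0.686 with an estimated correlation and 0.894 with a choroid covariate), and its list medians per knockout library are those plotted with the choroid genes. The lysosomal list had a median of log2 -0.05 (adjusted p = 0.0329, or 0.686 with an estimated correlation) and lost its call without any one of wild-type mTBI replicates 1 and 3 and knockout replicates 1 and 3, at adjusted p between 0.0734 and 0.224, and with a choroid covariate (0.309), a stricter filter (0.0545), a replicate block (0.0542), the sham libraries summed (0.0580) and without wild-type mTBI replicate 1 and knockout replicate 1 together (0.649). In these lists, 1 immature neuron gene, 1 lysosomal gene, 1 immediate early gene and 2 actin genes were lower adjusted over the list alone.

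Of the immune lists, 4 were higher in knockout mTBI than in wild-type mTBI, and those of microglia (adjusted p = 0.797), neutrophils (0.244) and lymphocytes (0.537) did not pass. Monocyte and macrophage markers had 10 of 10 positive and a median of log2 0.73 (adjusted p = 0.000462, or 0.686 with an estimated correlation), with Lyz2 at 12.0 ± 3.01 against 6.65 ± 1.17 CPM, the 1 gene called adjusted over the list alone. This list stood at log2 0.86 above sham in knockout replicate 2, at 0.19 in replicate 3 and at -0.04 in replicate 1, and at -0.73, -0.47 and 0.27 in wild-type mTBI replicates 1, 2 and 3. Its adjusted p was 0.0578 without wild-type mTBI replicate 1. Interferon genes had 20 of 24 positive and a median of log2 0.35 (adjusted p = 0.000109, or 0.686 with an estimated correlation and 0.0671 without wild-type mTBI replicate 1 and knockout replicate 1 together), with Irf7 at 3.40 ± 1.12 against 1.95 ± 0.626 CPM. Complement and antigen presentation genes had 17 of 21 positive and a median of log2 0.27 (adjusted p = 0.00119, or 0.686 with an estimated correlation, 0.0657 without wild-type mTBI replicate 2 and 0.0807 without wild-type mTBI replicate 1 and knockout replicate 1 together), with Tap1 at log2 0.56. From sham, the interferon list stood at log2 -0.13, -0.20 and 0.32 in wild-type mTBI replicates 1, 2 and 3. In knockout replicates 1, 2 and 3 it stood at 0.45, 0.056 and 0.30. The complement list stood at 0.12, -0.11 and 0.55 in wild-type mTBI and at 0.44, 0.65 and 0.18 in knockout mTBI. The libraries of these groups thus overlapped in both lists. NF-kB and cytokine genes had a median of log2 0.24 (adjusted p = 0.0112, or 0.686 with an estimated correlation), with Lcn2 at 47.2 ± 74.4 against 2.70 ± 2.85 CPM and Cxcl1 at log2 2.59, which was -0.95 without knockout replicate 2. The cytokine list had adjusted p = 0.810 without knockout replicate 2, 0.119 without wild-type mTBI replicate 1 and 0.104 without wild-type mTBI replicate 2, and 0.0545 with a stricter filter.

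Postsynaptic glutamate genes had 21 of 27 positive changes and a median of log2 0.12 in knockout mTBI against wild-type mTBI (adjusted p = 0.0112, or 0.686 with an estimated correlation), with Nlgn1 at 82.1 ± 4.22 against 71.1 ± 8.39 CPM and Homer1 at log2 -0.22. Voltage-gated channel genes had 20 of 23 positive and a median of log2 0.18 (adjusted p = 0.00199, or 0.686 with an estimated correlation), with Cacna1c at 189 ± 3.74 against 152 ± 35.2 CPM. Without wild-type mTBI replicate 1 the adjusted p was 0.296 and 0.432, and without knockout replicate 1 as well 0.102 and 0.548, and the postsynaptic list had 0.0679 without wild-type mTBI replicate 3 and 0.177 without knockout replicate 3. Neuronal (adjusted p = 0.418), astrocyte (0.797) and oligodendrocyte markers (0.0522) did not pass. Median, mean and test differed in sign for 9 lists, none of them called, among them those of astrocytes, microglia, erythroid cells and p53. Of the 44 lists 15 were called, 6 higher and 9 lower, and 9 without wild-type mTBI replicate 1.

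**Figure D3:**
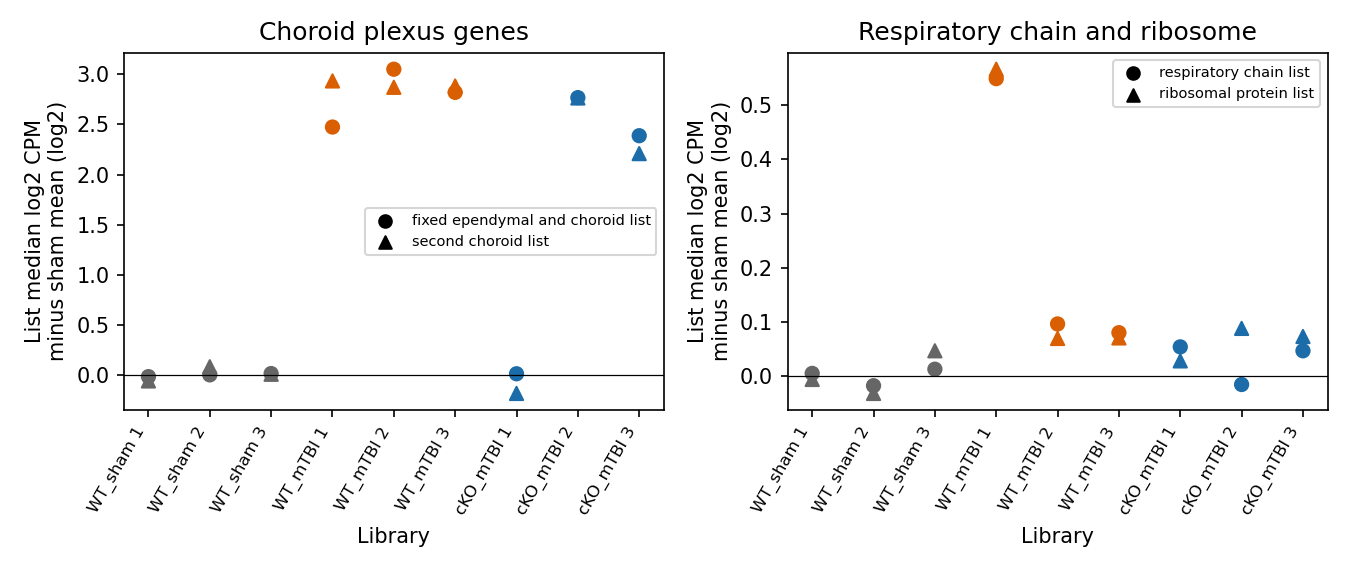
Median over list members of log2 CPM minus the sham mean, per library, for choroid genes at the left and for respiratory chain and ribosomal protein genes at the right. Grey is sham, orange wild-type mTBI and blue knockout mTBI. The fixed choroid list lies between 2.39 and 3.05 in 5 injured libraries and at 0.010 in knockout replicate 1, and the right-hand lists reach 0.55 and 0.57 in wild-type mTBI replicate 1.

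The injury and the knockout comparison share the wild-type mTBI libraries with opposite signs, so opposite changes arise without any effect. Tmsb4x was the 1 gene called in both, and it was opposite in direction. Independent lists of these sizes would share 0.00769 genes higher and then lower. In the simulated data without differences, between 0 and 1 genes were called in opposite directions. Across genes, which are not independent replicates, log2 fold changes of both comparisons had r = -0.53, and the simulated data gave -0.51 to -0.46. The covariance was -0.108, against a mean of -0.0509 in the simulated data. The simulated r is about that of groups with equal spread. The real biological coefficients of variation were 3.11% in sham, 16.9% in wild-type mTBI and 15.0% in knockout mTBI. Less spread in sham makes r more negative without any effect. The simulated data therefore cannot show whether the observed r and covariance exceed what the shared libraries give. In a test chosen after the data were seen, the 3 wild-type mTBI libraries were divided between both comparisons so that none was shared, in all 6 ways. Then r was -0.21 to -0.12, and the covariance -0.0616 to -0.0406 with a mean of -0.0495. Each division left 1 wild-type mTBI library alone in a comparison, so its counts of called genes are not given. What all 3 wild-type mTBI libraries had in common stayed in both comparisons. The count of opposite genes was 3 without wild-type mTBI replicate 1, 6 without wild-type mTBI replicate 3, 2 without any one of the knockout replicates, 17 without wild-type mTBI replicate 1 and knockout replicate 1 together, and 7 in DESeq2.

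The last comparison set the injured knockout against the libraries labelled wild-type sham, so that by the labels genotype and injury both differed. Etnppl was 2.86-fold higher in knockout mTBI (36.6 ± 3.32 against 12.8 ± 0.510 CPM, n = 3 each, adjusted p = 0.00012). Epn3 was 3.93-fold, Otx2 11.8-fold, Sfrp5 10.1-fold and Pcp4l1 1.62-fold higher, at adjusted p between 0.000564 and 0.0139. Pura was 2.24-fold lower (33.4 ± 5.13 against 74.7 ± 2.74 CPM, adjusted p = 0.00566), Nr4a2 1.42-fold lower (log2 -0.50, SE 0.07, adjusted p = 0.0214, or -0.45, SE 0.10 and 0.149 with a choroid covariate) and the synaptic scaffold gene Homer1 1.44-fold lower (82.1 ± 6.27 against 118 ± 3.53 CPM, adjusted p = 0.0299). Grm3 (log2 -0.51), Gucy1a2 (-1.88), Kcnh7 (-0.45), Kcnip3 (-0.33) and Scai (-0.42) did not pass, at adjusted p from 0.0558 to 0.132. Tmsb10 differed by log2 0.08 (adjusted p = 0.999), or -0.07 without knockout replicate 1.

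A total of 14 genes were called, 10 higher and 4 lower, with 1443 at an unadjusted p under 0.05 (edgeR). The count was 3, 2 and 5 without sham replicates 1, 2 and 3, 57 without wild-type mTBI replicate 1, 127, 27 and 5 without knockout replicates 1, 2 and 3, 338 without wild-type mTBI replicate 1 and knockout replicate 1 together, and 0 with the sham libraries summed. More genes were lower than higher without wild-type mTBI replicate 1 (23 higher and 34 lower) and in the fit of the 6 libraries compared (30 higher and 40 lower). Homer1 and Nr4a2 lost their calls without any one of the sham replicates or knockout replicate 3 and with a replicate block, at adjusted p between 0.0768 and 0.300, and Homer1 also without knockout replicate 2 (0.0679). Pcp4l1 lost its call without any one of the sham replicates (0.0985 to 0.162) and without knockout replicate 3 (0.0678), Otx2 and Pura without sham replicate 1 or 2 (0.0508 to 0.0697) and Sfrp5 without sham replicate 2 (0.0697).

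Complement and antigen presentation genes were higher in knockout mTBI than in the libraries labelled wild-type sham, with 21 of 21 positive and a median of log2 0.51 (adjusted p = 3.89e-06, or 0.841 with an estimated correlation). Cd74, the invariant chain of class II antigen presentation, was at 5.28 ± 2.38 against 1.98 ± 0.128 CPM (adjusted p = 0.303), and 5 genes were called adjusted over the list alone. Interferon genes had 22 of 24 positive and a median of log2 0.33 (adjusted p = 0.000304, or 0.841 with an estimated correlation), with 2 called adjusted over the list alone and Ifi27 at 35.4 ± 2.77 against 27.8 ± 1.83 CPM. The ependymal and choroid list had a median of log2 2.13 (adjusted p = 0.000187, or 0.841 with an estimated correlation), with Otx2 called over all genes and 6 genes adjusted over the list alone. Postsynaptic glutamate genes had 24 of 27 negative and a median of log2 -0.06 (adjusted p = 0.00398, or 0.841 with an estimated correlation), with Homer1 called. Immature neuron genes had a median of log2 -0.25 (adjusted p = 0.00716, or 0.841 with an estimated correlation, 0.0634 without knockout replicate 2 and 0.373 with a choroid covariate), with Hopx at log2 -0.72 and Eomes at 1.94. The lysosomal list had a median of log2 0.08 (adjusted p = 0.0361, or 0.841 with an estimated correlation) and lost its call without sham replicate 1 or 3, wild-type mTBI replicate 3 or knockout replicate 2, at adjusted p between 0.0636 and 0.314, and with a choroid covariate (0.676), no filter (0.107), a replicate block (0.0765) and the sham libraries summed (0.0751). The respiratory chain list was at a median of log2 0.02 (adjusted p = 0.824). Median, mean and test differed in sign for 8 uncalled lists, among them those of microglia and actin dynamics. The count of called lists was 10 without knockout replicate 1 and 10 without knockout replicate 3.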

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

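The alternatives that sum the sham libraries, weight each group, halve the counts, add a choroid covariate or leave out wild-type mTBI replicate 1 and knockout replicate 1 together were chosen after the data were seen. Tmsb4x kept its direction and call in the injury comparison (log2 7.56 to 8.35) and in the knockout comparison (-8.20 to -7.25) under all 23 alternatives. Leaving out 1 library at a time gave 7.58 to 8.35 and -8.20 to -7.43, and for the injured knockout against sham -0.0059 to 0.33, with -0.17 under the choroid covariate. RLE scaling, no composition scaling, the fold minimum, halved counts and totals without mitochondrially encoded, haemoglobin and ribosomal RNA genes kept every count of called genes within 1.5 times. Same-number libraries of the 3 pairs of groups correlated at -0.089 to 0.073, and libraries of other numbers at -0.11 to 0.12. No pairing by replicate number was seen, but 3 libraries per group cannot exclude it. The replicate block gave 107, 3 and 13 genes. In the order injury, knockout, injured knockout against sham and opposite genes, the counts of called genes were 541, 18, 226 and 7 in DESeq2 and 676, 68, 387 and 26 without a filter. They were 524, 23, 338 and 17 without the 2 libraries named above, and 45, 6, 71 and 5 with the choroid covariate. In the order injury, knockout and injured knockout against sham they were 252, 1 and 70 in fits of 6 libraries and 1, 1 and 0 with sham summed. For injury and the injured knockout against sham they were 722 and 279 in voom with sample weights and 247 and 137 with a weight per group, and for injury 64 with the stricter filter. Single libraries left out gave 5 to 251, 2 to 7, 2 to 127 and 1 to 6. Called lists numbered 7 to 14, 9 to 17 and 5 to 10 with single libraries left out, and called cell type lists 1 to 4, 1 to 4 and 1 to 2. An estimated correlation and fry gave 0 called lists and 0 cell type lists in each comparison, the smallest adjusted p being 0.686 and 0.181, against 9, 15 and 6 with the preset correlation. The mixed form of fry, which asks for change in either direction, called 6 lists after injury, 0 for the knockout and 3 for the injured knockout against sham, the smallest adjusted p being 0.000382 for astrocyte markers and 0.000185 for immediate early genes. Without those 2 libraries the lists numbered 9 for the knockout and 12 for the injured knockout against sham, 3 of the latter being cell types. Cell type lists numbered 2 without a filter for the injured knockout against sham, 2 with the stricter filter for injury, and with the choroid covariate 2 for injury and 0 for the injured knockout against sham. With the covariate the direction turned for Ttr (log2 -0.037), Folr1 (-0.18) and Nqo1 (-0.11) after injury, Otx2 (0.023) with the knockout, and Folr1 (-0.10) and Enpp2 (-0.075) in the injured knockout against sham. The choroid list turned as well, at adjusted p = 0.581 and 0.348, by construction, since the covariate is its own mean. Cxcl1 turned in the knockout comparison with voom (-0.33) and without knockout replicate 2 (-0.95, and up to 3.14 without other libraries), and Tmsb10 in the injured knockout against sham without knockout replicate 1 (-0.072, and up to 0.15 without other libraries) and without those 2 libraries (-0.072). Summing or leaving out sham libraries left fewer samples to test. The cause of the other differences was not tested. In simulated data DESeq2 made 33, 31 and 36 false calls in the 3 comparisons, against 3, 10 and 5 with edgeR. Genes changed 1.5-fold were recovered there by edgeR at 31.3% to 35.8%. The simulated groups had equal spread, unlike the real ones. These shares and false calls therefore do not give the error of the tests on the real groups.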

Other observations

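Of the tests reported here, those of all 3 explanations of the Tmsb4x levels and of an injury response of choroid genes were chosen after the result was seen. Inflammatory markers differed among the knockout mTBI libraries. Neutrophil markers stood at a list median of log2 2.29 above the libraries labelled wild-type sham in knockout replicate 2, at 1.11 in replicate 3 and at -0.05 in replicate 1. They were at 1.37 in wild-type mTBI replicate 3, and the list was not called in any comparison (adjusted p = 0.680, 0.244 and 0.103). The neutrophil genes Csf3r and Mmp9 were at 8.11 ± 3.53 and 2.16 ± 0.201 CPM in knockout mTBI (SD, n = 3) and at 6.34 ± 0.286 and 1.93 ± 0.440 CPM in sham. Microglial markers stood at log2 0.33 in knockout replicate 2 and between -0.08 and 0.10 in the other injured libraries. Csf1r and Ctss, of microglia, were at 84.2 ± 9.83 and 54.4 ± 14.1 CPM over 9 libraries, Flt1 of endothelium at 64.9 ± 7.58, Rgs5 and Vtn of mural cells at 89.5 ± 7.87 and 61.4 ± 6.51, Olig1 and Pdgfra of oligodendrocyte precursors at 81.7 ± 9.49 and 70.4 ± 7.14, and Mrc1 of macrophages at 5.08 ± 1.47. Lymphocyte genes Trac and Cd79a were at 0.543 ± 0.209 and 0.344 ± 0.172 CPM, and the haemoglobin genes Hbb-bs and Hba-a1 at 49.3 ± 23.5 and 15.8 ± 10.9.

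A list of 14 thalamic genes, written after thalamic genes had been seen to be high in it, had a median of log2 1.17 above sham in knockout replicate 1 and between 0.02 and 0.64 in the other injured libraries. Zfp949 was at 63.6 to 68.1 CPM in the sham libraries, at 45.4 in knockout replicate 2 and at 21.1 to 25.6 in the other injured libraries. The predicted genes Gm11868 and Gm7049, chosen after their values were seen, had the same order, with Gm11868 at 4.99 to 5.28 CPM in sham, 2.30 in knockout replicate 2 and at most 0.183 elsewhere. The cause of this order was not tested. The genes called after injury numbered 102 in the real split of the 6 libraries and at most 0 in the others, and 1 of 10 splits gave as many. The injured knockout against sham gave 14 and at most 0, again in 1 of 10 splits. In the knockout comparison the real split gave 3, the highest other 11, and 2 of 10 splits gave as many or more. With 10 splits no share under 0.05 can be had.

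The libraries labelled wild-type sham held Tmsb4x at the knockout level. The tables argue against Tmsb4x reads being counted on paralogs instead, since the summed level of thymosin-like genes differed by -34.1 CPM (sham minus wild-type mTBI). Reads with several alignments were left out of the counts, so their loss was not tested. A wrong label on sham libraries from mice without Tmsb4x remains open: the highest sham library held 0.978 times the Tmsb4x level of the highest knockout library. Of 12 other genes of small p in the knockout comparison, 7 were nearer the knockout group in sham (exact one-sided binomial p = 0.387, a criterion tightened after the count was seen). That count cannot decide on the label. Only Etnppl and Myoc among these genes had passed, and the binomial test takes genes as independent. An injury change undone by the knockout would also put sham nearer the knockout. Induction by injury from a near absent level stays open too, although Tmsb4x is generally an abundant transcript of uninjured brain, a background fact that no library here tested. The lowest wild-type mTBI library was 109-fold above the highest sham library, which goes with both explanations. The wrong label and the induction cannot be told apart, since no sham knockout group exists and all 3 sham libraries share the label.

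Choroid plexus genes were high in all wild-type mTBI libraries and in knockout replicates 2 and 3. Choroid plexus tissue in the preparation is a candidate source: of a second list of 15 choroid genes, all 15 tested and none in the fixed lists, 93.3% were over 2-fold higher both in knockout replicates 2 and 3 over replicate 1 and in wild-type mTBI over sham. The test was written before the values of that list were seen, but it names the split of the knockout libraries already seen in the fixed list. Genes of the same tissue or of the same response would follow that split, so the share adds little to the fixed list. Of the second list, 6 genes are among the called genes of the injury comparison. Ttr and Enpp2, the most abundant choroid genes, reached 3700 ± 638 and 1569 ± 318 CPM in wild-type mTBI, and a sort on neuronal tdTomato would remove such cells. A response to injury stays open, with a second-list median over log2 1 in 5 of 6 injured libraries and -0.19 in knockout replicate 1, and no biological difference between the knockout mice that would separate these was given in the labels.

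Respiratory chain and ribosomal protein lists were higher in wild-type mTBI than in sham. A trend with transcript length was tested through the exon length of a gene, summed over all its isoforms. After its removal the medians were log2 0.18 and 0.20, against 0.24 and 0.25 before. That length is only a stand-in for the length of the transcripts present. The removal therefore cannot exclude a length effect as the whole cause. A part from wild-type mTBI replicate 1 alone stays open: without it the medians were 0.081 and 0.086, under 50% of the values with it, but both lists stayed called. That library also had a rank correlation of -0.29 between level relative to the mean and exon length across genes, against 0.0081 to 0.11 in the other libraries. Injury itself, which the groups name, was not separated from that library.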
